A study of Mus musculus with 3 samples.

How the data were processed

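Single-cell RNA sequencing was carried out on dissociated back skin of male mice of 6 to 8 weeks. The mouse line combines an adipocyte-restricted, tamoxifen-inducible Cre (AdiCreER), the mT/mG membrane reporter and loxP-flanked alleles of Atgl, whose gene symbol is Pnpla2. By the sample titles, only the Cre-positive bleomycin library came from mice with the Cre, and the others were Cre-negative. The 3 libraries formed 3 groups of 1 library each, named from the sample titles: Cre-negative PBS, Cre-negative bleomycin and Cre-positive bleomycin. Per the labels' protocols, skin was minced, digested with the enzyme blend Liberase TL and passed through a mesh filter, and libraries were made on the 10x Genomics platform, which tags each captured RNA with a unique molecular identifier (UMI). Neither the 10x chemistry nor the number of mice per library was given in the sources used here.

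The deposited files hold UMI counts per gene and cell barcode as whole numbers for 32285 genes, and the authors deposited them as filtered matrices without normalization. Cell Ranger 2.1.1 and build mm10 are named in the submitters' processing notes, and the layout of the gene file resembles that of a later Cell Ranger, so the version behind these counts remains unsettled. The annotation release, the sequencing depth in reads and the barcode filter were not given in the sources used here. No barcode held fewer than 500 UMIs in the Cre-negative PBS library or 501 UMIs in either bleomycin library, so cells with less RNA than that are missing from every share. Fixed filters of this kind lower the share of small or RNA-poor cells such as neutrophils, and a fine mesh with enzymatic digestion passes few lipid-laden adipocytes or whole muscle fibres. Counts come from tags at 1 end of transcripts, so a tag may lie outside the deleted part of Pnpla2, and such a tag carries no information on deletion. Gene positions were taken from GENCODE mouse release 21 on GRCm38, the assembly of mm10, in which 32158 of the gene identifiers were found.

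Analysis used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9. Barcodes with at least 200 detected genes and at most 10% of UMIs from mitochondrial genes were kept. Per library, the barcodes with the highest Scrublet scores were taken as doublets at an expected rate of 0.8% per 1000 barcodes. This marked 1, 9 and 4 barcodes, of which 1, 7 and 1 had passed the other filters and were left out. Genes seen in fewer than 3 cells were left out of clustering. Counts were scaled to 10000 per cell and ln(x + 1) transformed, 2000 variable genes and 30 principal components were taken, and Leiden clustering at resolution 1 ran on 15 neighbours with seed 0 and without integration of libraries. Each of the 20 clusters took the class, out of 17, with the largest share of its fixed markers found in 25% of the cluster's cells at 2 times the level of other cells. At least 3 such markers were required, and a cluster with more markers of another class among its 10 leading genes stayed unnamed. This named 19 clusters and left 1 unnamed. The fold of 2 and the detection share of 25% were set after the counts were seen, and they left the 1 unnamed cluster out of every class. Its share of cells is given for each library.

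With 1 library per group, no test across samples was possible, no p-value was computed, and no difference has a replicate check. Shares of cells are given with exact Clopper-Pearson 95% intervals. Expression was compared within a class by summing UMIs over its cells in each library, as CPM, the count scaled to the total UMIs of that class, with exact Poisson intervals, and as a CPM ratio with its exact conditional interval. All intervals, written in square brackets, cover counting error only. They do not cover the spread between mice, between dissociations or, for expression, between cells. Classes with at least 20 cells in both libraries were compared. A gene at 0 UMIs in 1 library is given a lower bound on its fold, computed by placing that library at 3 counts. For log2 ratios, including those inside medians, 0.5 UMIs were added to both counts of every gene, while CPM ratios carry no such addition.

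Gene groups and markers were fixed before the data were examined, as were the filters, the clustering, the rule for named genes and most of the other settings tried. The 25 gene groups were fibrillar and associated collagens, basement membrane, collagen processing and crosslinking, matricellular and provisional matrix, small proteoglycans and homeostatic matrix, contractile genes, TGF-beta response, proteases and inhibitors, chemokines and cytokines, complement and acute phase, p53 and DNA damage, interferon response, lipolysis and lipid droplet, fatty acid uptake and handling, fatty acid oxidation, adipogenic regulators and progenitor markers, lipid-associated macrophage, alternative and inflammatory macrophage polarisation, monocyte, antigen presentation, glycolysis and hypoxia, dissociation stress, proliferation, and a sex check. Some genes stand in more than 1 group, for example Apoe, Fn1, Junb, Spp1 and Chil3. A group was summarised as the median log2 CPM ratio over members with at least 20 UMIs in the libraries compared, where at least 3 members had them. Its interval came from 1000 Poisson redraws of the counts. Its percentile among 10000 random groups of the same size, matched on expression in 20 bins, is given as a description of these libraries.

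Named genes were, in fibroblast-like cells, the 12 highest and 12 lowest ratios ranked by the interval bound nearest to 1 among genes with at least 50 UMIs, and in other classes the 6 highest and 6 lowest. Mitochondrial, ribosomal protein, haemoglobin, predicted and sex-linked genes and markers of other classes were left out of that ranking, with markers of other classes reported apart. Up to 4 members with the most UMIs in each group, and Pnpla2, Col1a1, Col3a1, Fn1, Postn, Acta2, Timp1, Cdkn1a, Cd36 and Fabp4, were added. A few further genes, mostly lower-count members of a described group, were named after their values were seen, namely Cxcl9, Phlda3, Col6a1, Col6a3, Adipoq, Pck1, Cidec, Plin1, Plin4, Retn, Adrb3, Lep, S100a8, S100a9 and Acta1. Not every gene that the rule selects is reported here.

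The interval step was tested on simulated counts with 200 altered genes, 100 at 2-fold and 100 at 4-fold, chosen among genes with at least 50 UMIs. For fibroblast-like cells under bleomycin against PBS (chosen among 771 genes), 79% of the 2-fold genes had an interval apart from 1. For Cre-positive against Cre-negative (among 1439 genes) this share was 72%. In macrophage-monocyte-like cells these shares were 44% (2365 genes) and 87% (3126 genes). At 4-fold the share was 98% in macrophage-monocyte-like cells under bleomycin against PBS and 100% in each of the other 3 simulations. Intervals covered the true ratio in 95.9%, 96.2%, 97.2% and 96.0% of genes, in the order just given.

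The other settings chosen then were at least 500 genes per cell, at most 5% or any share of mitochondrial UMIs, no doublet removal, Leiden resolutions 0.5 and 2.0, clustering without the listed genes, classes assigned per cell from marker UMIs, TMM factors (edgeR 4.0.16 in R 4.3.3), totals without mitochondrial, ribosomal and haemoglobin genes, the mean of per-cell CPM, cells thinned to 1000 UMIs, and member minimums of 5 and 50 UMIs. Further settings were added after the data were seen. TMM factors moved the median log2 ratio of all genes by 0.49 in macrophage-monocyte-like cells, 0.13 in endothelial-like cells and -0.13 in keratinocyte-like cells for bleomycin against PBS, and by -0.12 in macrophage-monocyte-like cells for Cre-positive against Cre-negative. In the other comparisons it moved by less than 0.1. Transcripts of the mT/mG reporters were not analysed here, so recombination was not read from them.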

Results

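Transcripts were counted in single cells of back skin from AdiCreER; mT/mG; Atgl-floxed male mice, in which tamoxifen activates Cre in adipocytes that carry the transgene. Skin was treated with tamoxifen (5 mg/ml) 2 days before the first of 5 days of subcutaneous injections of 100 µl, holding either PBS or bleomycin (300 µg/ml), a DNA-damaging drug used to induce skin fibrosis in mice. There was 1 library for each of 3 groups, with 401 barcodes and 1134567 UMIs for Cre-negative PBS, 1071 barcodes and 1705467 UMIs for Cre-negative bleomycin, and 739 barcodes and 1637235 UMIs for the library labelled Cre-positive bleomycin. After filtering, 235, 679 and 422 cells remained, with median depths of 2339, 1656 and 2166.5 UMIs. The design poses the question of what bleomycin does to skin cells with adipocyte lipolysis intact, and how that response differs when Atgl is to be deleted in adipocytes. The bleomycin comparison sets Cre-negative bleomycin against Cre-negative PBS, and the Cre comparison sets the library labelled Cre-positive against the Cre-negative one, both after bleomycin. The Cre-negative bleomycin library enters both, so chance in it pushes them in opposite directions. For some classes the library labelled Cre-positive is also set against PBS.

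Pnpla2 (ENSMUSG00000025509; GRCm38 chromosome 7, 141455198 to 141460743, plus strand), which encodes adipose triglyceride lipase, was not lower in the library labelled Cre-positive. Over all kept cells it stood at 37.3 CPM [25.4 to 52.96] (31 UMIs) in Cre-negative PBS, 45.7 CPM [34.8 to 58.9] (59 UMIs) in Cre-negative bleomycin and 82.5 CPM [66.6 to 101.1] (93 UMIs) in the library labelled Cre-positive. Of the 8 adipocyte markers, Adipoq, Cidec, Pck1, Plin4, Retn and Adrb3 had their highest CPM there and Plin1 and Lep in PBS, on few UMIs. The hormone gene Adipoq was at 10.8, 0.775 and 28.4 CPM (9, 1 and 32 UMIs) and the lipid droplet gene Plin1 had 8, 0 and 7 UMIs in the same order. Cells with at least 3 adipocyte markers, a criterion chosen after the values were seen, numbered 1, 1 and 2. The 2 such cells of the library labelled Cre-positive held 29 of its 93 Pnpla2 UMIs, all 32 of its Adipoq UMIs and all 36 of its UMIs of Pck1, a gene of glyceroneogenesis. Because the deleted part of Pnpla2 was not given and a tag outside that part carries no information on deletion, these levels check nothing about recombination, and directions drawn below rest on the label alone. In the sex check, the Y-linked Ddx3y had 76, 73 and 91 UMIs, Eif2s3y 65, 84 and 74, Uty 57, 77 and 81 and Kdm5d 15, 20 and 16, against 1, 0 and 0 UMIs of Xist, as the male labels require.

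Macrophage-monocyte-like cells made up 8.94% [5.62 to 13.3] of kept cells in Cre-negative PBS (21 cells), 46.7% [42.9 to 50.5] in Cre-negative bleomycin (317 cells) and 26.1% [21.9 to 30.5] in the library labelled Cre-positive (110 cells). Neutrophil-like cells made up 5.45% [3.87 to 7.43] of Cre-negative bleomycin cells (37 cells) and 0.237% [0.0060 to 1.31] of the library labelled Cre-positive (1 cell), against 0.426% in PBS (1 cell). Fibroblast-like cells were a lower share in Cre-negative bleomycin, 9.28% [7.20 to 11.7], than in PBS, 21.7% [16.6 to 27.5], or in the library labelled Cre-positive, 25.1% [21.05 to 29.5]. Keratinocyte-like cells stood at 23.8%, 3.53% and 5.69%, and endothelial-like cells at 25.1%, 14.6% and 13.03%. Skeletal muscle-like cells were 3.83% of both Cre-negative libraries and 15.9% [12.5 to 19.7] of the library labelled Cre-positive. Dendritic-like cells were 7.66%, 4.12% and 3.79%, mural-like cells 2.13%, 3.09% and 5.21%, Schwann-like cells 2.98%, 2.21% and 3.08%, and cells of the T, NK and innate lymphoid class 2.13%, 1.91% and 0.474%. The unnamed cluster, led by Cfd, Sfrp5 and Thbs4, held 1.28%, 5.30% and 1.42%. The leukocyte classes together (macrophage-monocyte-like, dendritic-like, neutrophil-like and lymphoid) held 19.1%, 58.2% and 30.6%. Shares are parts of 1 total, so a higher leukocyte share by itself lowers those of the other classes. The lower fibroblast-like, keratinocyte-like and endothelial-like shares in Cre-negative bleomycin therefore do not show a loss of those cells.

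Shares depend on the minimum of UMIs per barcode and on depth, since neutrophil-like cells had a median of only 622 UMIs in Cre-negative bleomycin and no cluster took that name when cells with at least 500 genes were clustered. The dendritic-like cluster carried 3 dendritic and 3 macrophage-monocyte markers, was led by Retnla and MHC class II genes, and joined the macrophage-monocyte-like class under several settings. For both classes combined the shares were 16.6% [12.1 to 22.0], 50.8% [47.0 to 54.6] and 29.9% [25.5 to 34.5].

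**Figure D1:**
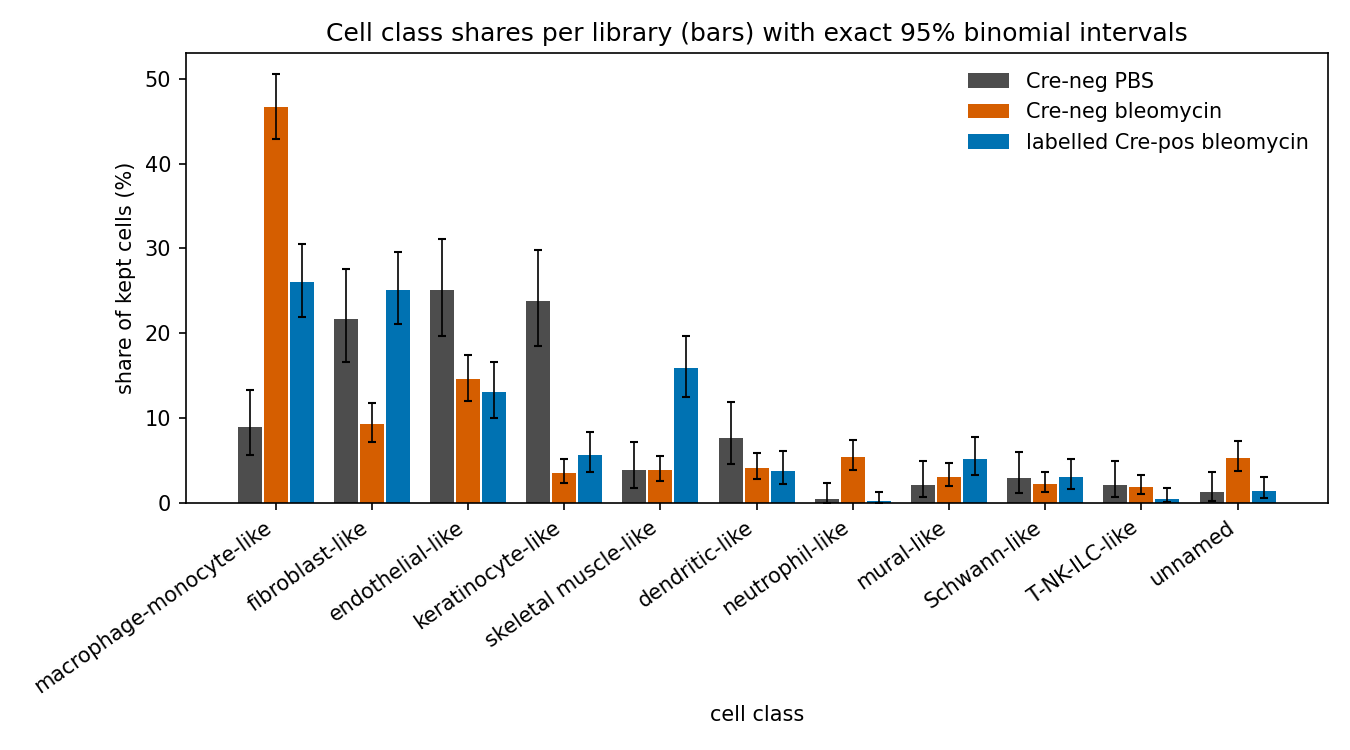
Share of kept cells (y axis, %) in each cell class (x axis) for the 3 libraries, 1 per group, with bars for shares and lines for exact 95% binomial intervals that cover counting error only. The macrophage-monocyte-like share was 46.7% in Cre-negative bleomycin, 26.1% in the library labelled Cre-positive and 8.94% in PBS.

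In the bleomycin comparison, fibroblast-like cells (63 against 51 cells) held far more transcript of Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, and of interferon and class I antigen presentation genes. Cdkn1a (ENSMUSG00000023067; chromosome 17, 29090976 to 29100727) stood at 1077 CPM [911 to 1265] against 21.4 CPM [4.41 to 62.5], a ratio of 50.4 [16.9 to 247]. Isg15 (ENSMUSG00000035692; chromosome 4, 156199424 to 156200818), a ubiquitin-like interferon target, was at 651 against 35.7 CPM, a ratio of 18.3 [7.54 to 57.6]. Myoc, Pi16 and Cilp were lower, while the fibrillar collagen genes Col1a1 and Col3a1 were near their PBS levels over the class.

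All 8 measured members of the p53 and DNA damage group were higher, with a median log2 ratio of 2.55 [2.03 to 3.33], including the pro-apoptotic Bax at 8.36 [2.98 to 32.5], Btg2 at 7.27 [3.08 to 20.9], Ccng1 at 4.87 [1.82 to 16.3] and Phlda3 at 8.11. This median was 3.57 as the mean of per-cell CPM and 3.67 over 3 members within cluster 2. All 11 measured interferon response members were higher, with a median of 3.41 [2.46 to 3.99], which is also the value with the 1 member at 0 UMIs placed at its bound. The interferon median was lower in thinned cells (1.93), over members with at least 50 UMIs (2.099) and within cluster 5 (2.01). Among the members were Ifi27l2a at 2.46, Ifitm3 at 2.97, the tetherin gene Bst2 at 4.35 [2.77 to 7.10] and the transcription factor gene Irf7 at 11.6 [4.67 to 37.0]. All 4 antigen presentation members were higher, with a median of 2.47 [2.17 to 2.83]: H2-K1 at 6.02 [4.12 to 9.05], H2-D1 at 5.22 [3.60 to 7.77], B2m at 4.48 [3.41 to 5.98] and the immunoproteasome gene Psmb8 at 16.2 [4.14 to 140]. As a description of these libraries, the p53 and interferon medians lay above all 10000 random groups of matched expression.

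Complement and acute phase genes had a median of 0.55 [0.35 to 0.94], with 8 of 9 members higher, among them Cfb, of the alternative pathway, at 10.95 [5.73 to 23.5] and Serping1 at 1.47 [1.22 to 1.78]. Chemokines and cytokines had a median of 0.52 [0.31 to 1.54] over 9 members, with the interferon-induced Cxcl9 at 13.2 [3.30 to 115] and the monocyte attractant Ccl7 at 10.7 [4.33 to 34.5], whose 5 UMIs in PBS came from 1 cell. The chemokine median depended on few cells and on the bounds of the class, at 3.02 without the 3 richest cells of each library, 1.87 within cluster 5 and 1.58 with the unnamed cluster included, and the complement median ranged from 0.21 with that cluster to 1.45 in thinned cells. Serpine2, a protease inhibitor, was at 5.58 [3.35 to 9.80] and Timp1, an inhibitor of metalloproteinases, at 4.87 [1.82 to 16.3]. The early response genes of the dissociation stress group had a median of 0.84 [0.76 to 1.52], with 15 of 16 members higher, led by Zfp36 at 7.55, Fosb at 6.08, Fos at 3.52 and Junb at 3.11, and this median was 2.03 without the 3 richest cells of each library. Proteases and inhibitors had a median of 0.40 [0.09 to 0.60] and monocyte genes one of 0.61 [0.46 to 0.76] over 5 members, with S100a6 at 1.53 and S100a4 at 2.49. Plac8, a monocyte marker left out of the ranking, was at 2.96 [1.86 to 4.87] in these fibroblast-like cells.

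Small proteoglycans and homeostatic matrix genes were lower, with a median of -0.82 [-1.05 to -0.33] and 8 of 11 members lower, including Dpt (dermatopontin) at 0.393 [0.311 to 0.493], Ogn at 0.503, Lum at 0.566 and Dcn at 0.851. This median was -0.23 in cells thinned to 1000 UMIs, with 8 PBS and 11 bleomycin cells left out, and -0.022 within cluster 5. Myoc was at 0.0298 [0.00354 to 0.112], Pi16 at 0.144 [0.0956 to 0.211], Cilp at 0.171 [0.0957 to 0.287] and Hmcn2 at 0.145 [0.0596 to 0.305], the last reversed within fibroblast-like cluster 5. Other low ratios were Csmd1 at 0.213, with 40 of its 81 PBS UMIs in 1 cell, Gpc3 at 0.218, Fndc1 at 0.248, Tmeff2 at 0.327, Inmt at 0.328, Tshz2 at 0.366 and Plpp3 at 0.389. Collagen processing and crosslinking genes had a median of -0.39 [-0.72 to -0.02], with Loxl1 at 0.563 and Adamts2 at 0.578.

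Fibrillar and associated collagens had a median of -0.05 [-0.31 to 0.04] over 12 members, which joined opposite values in the main clusters, 0.48 within cluster 2 and -0.79 within cluster 5. Col1a1 (ENSMUSG00000001506; chromosome 11, 94936224 to 94953042) was at 6522 against 5741 CPM, a ratio of 1.14 [1.03 to 1.25] that reversed within cluster 5, with per-cell classes and with the unnamed cluster included. Col3a1 (ENSMUSG00000026043; chromosome 1, 45311538 to 45349706) was at 0.959 [0.882 to 1.04] and Col1a2 at 0.802 [0.732 to 0.878]. Fn1 was at 0.946 [0.710 to 1.26] and Postn at 1.52 [0.807 to 2.93], both matricellular genes, and Acta2, the smooth muscle actin of myofibroblasts, had 0 UMIs in fibroblast-like cells of every library. Intervals that included 0 were found for the medians of basement membrane (-0.02), matricellular and provisional matrix (-0.08), contractile genes (-0.01), TGF-beta response (0.02), fatty acid uptake (-0.18), fatty acid oxidation (-0.10), adipogenic regulators (-0.09), lipid-associated macrophage genes (0.25) and glycolysis (0.14). Under other settings the adipogenic median ranged from -0.66 to 0.34, and in thinned cells the medians were 0.78 for TGF-beta response, -0.93 for fatty acid uptake and -0.67 for lipid-associated macrophage genes. The fatty acid uptake median was the same with its member at 0 UMIs at its bound. Lipolysis genes had a median of -0.54 [-1.20 to 0.49] over 3 members. The fatty acid carrier gene Fabp4 had 34 UMIs in PBS and 0 in Cre-negative bleomycin, at least 11.2-fold lower, but all 34 came from 1 cell, and the scavenger receptor gene Cd36 had 4 and 0 UMIs. Within fibroblast-like cells, cluster 2 held 33 of 51 PBS cells and 32 of 63 Cre-negative bleomycin cells, and cluster 5, led by Pi16 and Dpp4, held 12 and 27.

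**Figure D2:**
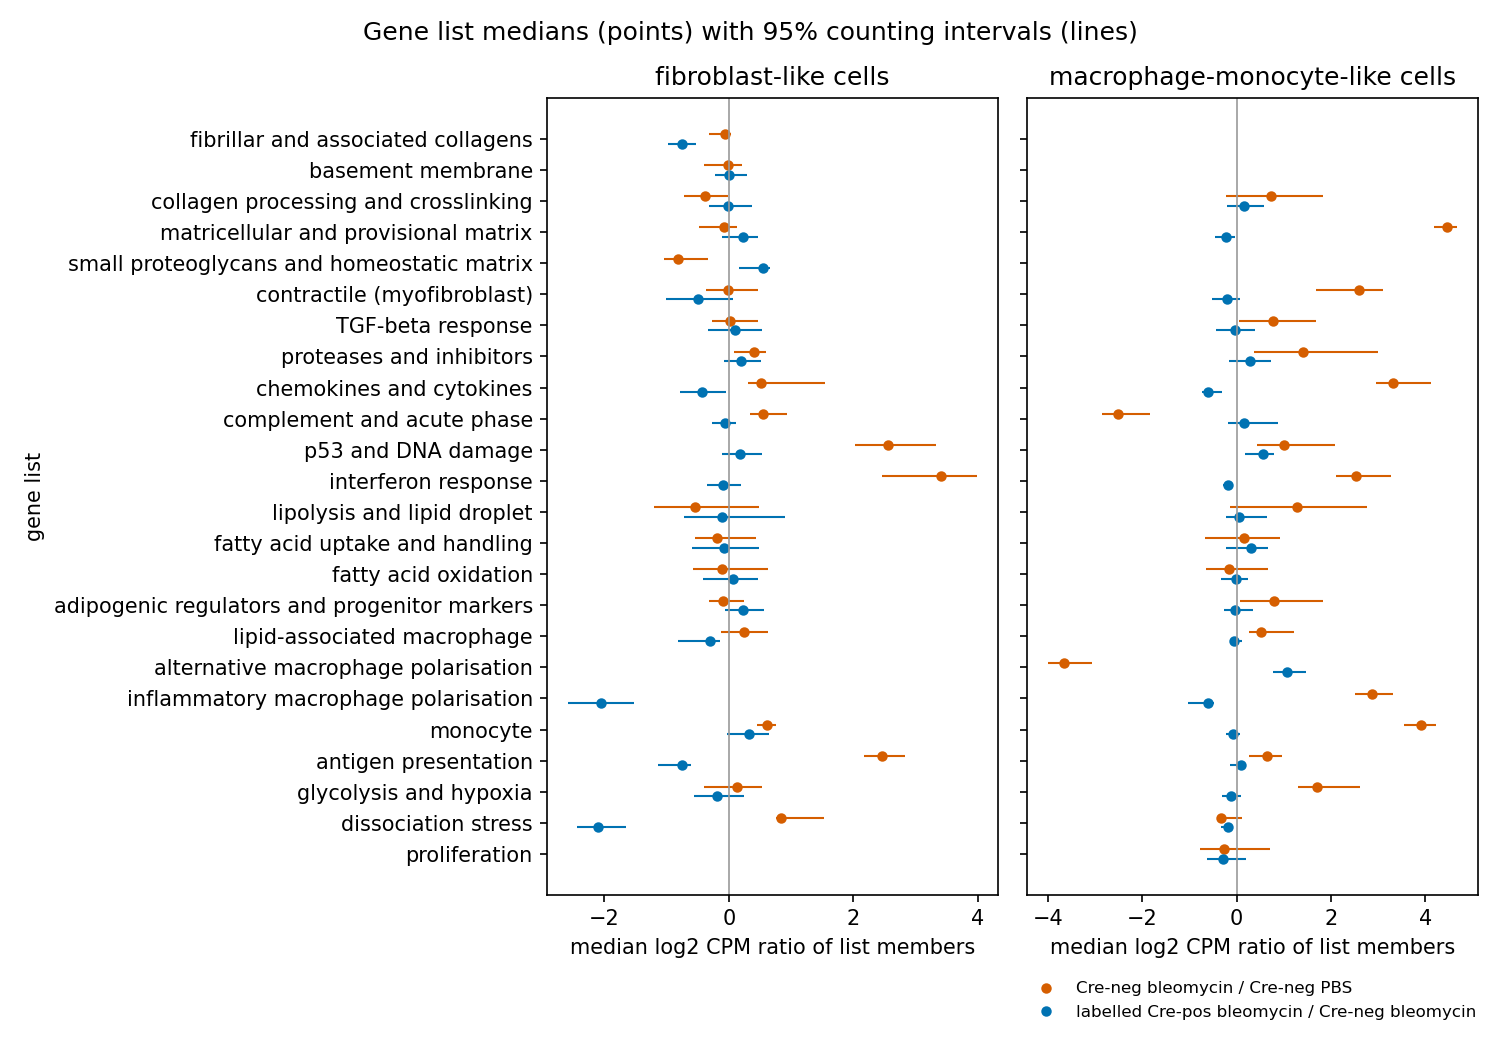
Median log2 CPM ratio (x axis) of each gene group (y axis) in fibroblast-like and macrophage-monocyte-like cells, with points for medians and lines for 95% intervals from redrawn counts, for the bleomycin comparison (orange) and the Cre comparison (blue). In fibroblast-like cells the collagen median was -0.05 in the bleomycin comparison and -0.76 in the Cre comparison, and the dissociation stress medians were 0.84 and -2.11.

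Macrophage-monocyte-like cells of Cre-negative bleomycin carried monocyte and inflammatory genes that were absent or rare in the 21 cells of PBS, and far less of the genes of resident, alternatively polarised macrophages. Ly6c2 (ENSMUSG00000022584; chromosome 15, 75108158 to 75111970), a surface protein gene of classical monocytes, had 1175 UMIs against 0, at least 32.2-fold higher. Apoe, an apolipoprotein gene, was at 1092 CPM [1013 to 1177] against 16719 CPM [15629 to 17865], a ratio of 0.0653 [0.0590 to 0.0723]. The classes were held by different clusters: 81.0% of PBS cells lay in cluster 4, led by Ccl8, Pf4, Folr2 and Cd163, and 11.7% of Cre-negative bleomycin cells did, whose others lay mainly in clusters 12, 17 and 18 with 98, 106 and 76 cells. These ratios therefore combine the mix of clusters with levels within them.

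Ms4a4c was at least 19.99-fold, the cytokine gene Il1b at least 14.3-fold, Slfn4 at least 12.98-fold and Chil3 at least 12.7-fold higher, and Plac8 was at 45.8 [12.7 to 379]. The monocyte group had a median of 3.90 [3.54 to 4.22] (2.52 with its 5 members at 0 UMIs placed at their bounds) with 11 of 12 members higher, among them S100a6 at 8.75 and S100a4 at 6.52. Inflammatory polarisation genes had a median of 2.87 [2.50 to 3.31] (1.83 at the bounds), and chemokines and cytokines one of 3.32 [2.95 to 4.12] (2.70 at the bounds), with the monocyte attractant Ccl2 at 15.1 [6.44 to 46.6] and the neutrophil attractant Cxcl2 at 23.3 [7.94 to 113]. All 16 interferon response genes were higher, with a median of 2.53 [2.104 to 3.28] (2.15 at the bounds) and Isg15 at 21.5 [7.34 to 105]. All 11 glycolysis and hypoxia genes were higher, with a median of 1.71 [1.30 to 2.62] (1.33 at the bounds), such as Pkm at 7.02 and Aldoa at 6.57. Cdkn1a was at 14.6 [5.69 to 53.8], and the p53 group had a median of 1.00 [0.42 to 2.09] (0.24 at the bounds), which was 2.69 in thinned cells and 2.34 over members with at least 50 UMIs, 5 members in each case.

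Alternative polarisation genes had a median of -3.66 [-4.005 to -3.07] with 9 of 10 members lower, among them Retnla at 0.0012 [0.000144 to 0.00442], with 83 of its 137 PBS UMIs in 1 cell, Mrc1 at 0.177 [0.145 to 0.215] and Folr2 at 0.205. Chil3 was the member that was higher. Ccl8 was at 0.0530 [0.0395 to 0.0708], Ednrb at 0.0285, Mir99ahg at 0.0411 and Fchsd2 at 0.0274, with 32 of the 42 PBS UMIs of Fchsd2 in 1 cell. Complement and acute phase genes had a median of -2.52 [-2.85 to -1.83], with C4b at 0.0340. Matricellular genes had a median of 4.46 (1.86 at the bounds), contractile genes 2.60 (1.63), proteases 1.40 (0.81), TGF-beta response 0.77 (0.42), lipid-associated macrophage genes 0.52 (0.09) and adipogenic regulators 0.79 (-0.12). Medians were 0.64 [0.27 to 0.96] for antigen presentation, 0.72 for collagen processing, 1.29 for lipolysis, 0.17 for fatty acid uptake, -0.15 for fatty acid oxidation, -0.33 for dissociation stress and -0.27 for proliferation, the last over 3 members. Of these, fatty acid oxidation was at 1.07 and fatty acid uptake at -0.77 in thinned cells, dissociation stress at 0.44 without the 3 richest cells, lipolysis at -0.20 with per-cell classes and proliferation at -1.86 with at least 500 genes per cell, so they gave no settled value. Of markers of other classes, the dendritic Mgl2 was at 0.00577, the B cell gene Ighm was at 0.168 and the mast cell Cma1 had 61 UMIs against 0, at least 1.67-fold higher. The alternative polarisation, complement and antigen presentation medians were the same at the bounds. With dendritic-like cells included the medians were 1.86 for monocyte genes, 1.30 for chemokines, 0.87 for inflammatory polarisation, 1.11 for matricellular genes, -1.25 for complement and -2.29 for alternative polarisation, and those of antigen presentation, contractile, TGF-beta response and glycolysis genes changed sign, to -0.32, -0.26, -0.023 and -0.01.

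Endothelial-like cells (99 against 59) also held more p53 and interferon transcript. Cdkn1a was at 733 CPM [605 to 879] against 52.3 CPM [22.6 to 103], a ratio of 14.0 [6.88 to 33.2], and Irf7 was at 9.02 [4.35 to 21.7], H2-Q7 at 11.2 and Ifi27l2a at 5.85. Medians were 1.29 [0.82 to 1.85] for p53 and DNA damage, 1.49 [1.15 to 1.88] for interferon response with all 14 members higher, 1.05 for antigen presentation and 0.85 [0.56 to 1.01] for dissociation stress. The p53 median was 2.57 with at most 5% mitochondrial UMIs and 2.33 in thinned cells, and that of dissociation stress ranged from 0.43 to 1.61 over the settings run. The adhesion receptor gene Sele was at 9.95 [3.995 to 31.9] and Tmem252 at 12.5 [5.84 to 32.1]. Both lead cluster 15, which held 51 of 99 Cre-negative bleomycin cells and 5 of 59 PBS cells, and 48 of the 99 cells had under 1000 UMIs. Cluster 0 held 42 of 99 and 51 of 59, so the endothelial-like ratios combine the mix of clusters with levels within them. Fxyd6 was at 0.113, Smco4 at 0.204, Myo10 at 0.266, Rasgrf2 at 0.297 and Ltbp4 at 0.364, and the lymphatic Ccl21a, at 0.141, rested on 1 cell in each library. Smaller medians were 0.75 for fatty acid oxidation, 0.57 for glycolysis, 0.53 for adipogenic regulators and 0.48 for lipid-associated macrophage genes.

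Keratinocyte-like cells (24 against 56) went the other way in the dissociation stress group, whose median was -2.35 [-2.52 to -1.64] with 16 of 17 members lower. Atf3 (ENSMUSG00000026628; chromosome 1, 191170296 to 191218039), a stress-induced transcription factor gene, was at 151 CPM [77.9 to 263] against 1603 CPM [1467 to 1748], a ratio of 0.0940 [0.0483 to 0.166]. Jun was at 0.161, Nr4a1 at 0.0351 [0.00088 to 0.199] and Egr1 at 0.0797, with the Cre-negative bleomycin UMIs of Egr1 in 1 cell, and Ppp1r15a was at least 5.34-fold lower. Ifitm3, an interferon-induced gene, was at 4.40 [2.80 to 6.92], Adgrl3 at 4.68, Auts2 at 3.77, Txnip at 3.39 and Apoe at 2.14. Mgll at 4.27 and Cst6 at 0.125 each reversed without the cell richest in them, which held 30 of 31 and 678 of 734 UMIs. Of markers of other classes, Ndufa4l2 was at 0.146 and Gata3 at 0.484.

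In the Cre comparison, fibroblast-like cells of the library labelled Cre-positive (106 cells, against 63) held less collagen and far less early response transcript, while Pi16, Myoc and Fmo2 were higher. Col1a1 stood at 3437 CPM [3228 to 3657] against 6522 CPM [6104 to 6962], a ratio of 0.527 [0.481 to 0.577], and Col3a1 at 4066 CPM [3838 to 4304] against 8034 CPM [7568 to 8520], a ratio of 0.506 [0.466 to 0.550]. Fos, an immediate early gene, was at 0.121 [0.0913 to 0.158] and Pi16 at 4.76 [3.29 to 7.13]. Cdkn1a was at 1150 against 1077 CPM, a ratio of 1.07 [0.878 to 1.30].

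Collagens had a median of -0.76 [-0.98 to -0.52] with 10 of 14 members lower, below all 10000 random groups as a description of these libraries, and with Col6a3 at 0.432, Col6a1 at 0.497 and Col1a2 at 0.803. The collagen median was -1.48 [-1.72 to -1.23] within cluster 2 (32 against 56 cells for Cre-negative and labelled Cre-positive) and 0.089 [-0.088 to 0.36] within cluster 5 (27 against 47 cells), where Col1a1 and Col3a1 were not lower. Serpinh1, the collagen chaperone gene, was at 0.515 and Pcolce at 0.604, although collagen processing as a group had a median of -0.01. All 15 measured dissociation stress genes were lower, with a median of -2.11 [-2.44 to -1.65], among them Fosb at 0.0967, Zfp36 at 0.135, Junb at 0.158 and Jun at 0.273. The growth arrest gene Gadd45g was at 0.187 [0.116 to 0.294]. All 6 antigen presentation genes were lower, with a median of -0.75 [-1.13 to -0.61], -1.62 within cluster 2, and B2m at 0.631, H2-K1 at 0.580 and H2-D1 at 0.651. Chemokines and cytokines had a median of -0.42 [-0.78 to -0.05], with Cxcl14 at 0.475 and Cxcl13 at 2.72. Inflammatory polarisation genes had a median of -2.05 over only 3 members, Nfkbia, Cxcl9 and Cxcl10.

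Small proteoglycans and homeostatic matrix genes had a median of 0.55 [0.16 to 0.66], with Dcn at 1.49, Mfap5 at 2.16 and Ogn at 1.74, and this median was -0.097 in cells thinned to 1000 UMIs, with 18 and 11 cells left out. Higher ratios were Myoc at 12.8 [3.38 to 109], Fmo2 at 9.10 [4.06 to 25.3], Abca6 at 6.46, Prkg2 at 6.41, Col4a4 at 6.29, Ccn5 at 5.94, Inmt at 4.52, Galnt15 at 4.48 and Prkg1 at 4.11. Of these, Ccn5 and Inmt reversed within cluster 5. Csmd1, at 5.45, had 59 of its 195 UMIs in 1 cell. Fn1 was at 2.20 [1.77 to 2.77], with 108 of 450 UMIs in 1 cell and the opposite sign within cluster 2, and Timp1 was at 2.24 but 0.775 without 1 cell. Timp2 was at 2.07 [1.73 to 2.49], Trp53inp1 at 2.26 [1.44 to 3.66] and Postn at 1.00 [0.624 to 1.65].

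Lower ratios that rested on few cells were Crabp1 at 0.0269 (1 cell against 3), S100a4 at 0.0616 (71 of 108 UMIs in 1 cell), Trps1 at 0.0678 (36 of 56), Prlr at 0.0931 (40 of 51), Dkk2 at 0.155 (80 of 110), Enpp2 at 0.155 (31 of 43) and Apoe at 0.210 (60 of 122). Crabp1, Dkk2, Prlr and Enpp2 lead fibroblast-like cluster 6, which held 4 and 3 cells. Of these, Trps1, Prlr, Dkk2, Enpp2 and Apoe reversed under at least 1 other setting. The other medians included 0 in their intervals, except lipid-associated macrophage genes at -0.31: basement membrane 0.01, matricellular genes 0.23, contractile genes -0.50, TGF-beta response 0.10, proteases 0.20, complement -0.06, p53 0.18, interferon -0.09, lipolysis -0.10, fatty acid uptake -0.08, fatty acid oxidation 0.06, adipogenic regulators 0.23, monocyte 0.33 and glycolysis -0.18. Pnpla2 had 4 UMIs against 3 in these cells, and Fabp4 and Cd36 had at most 2. Of markers of other classes, the keratinocyte gene Dmkn had 53 UMIs against 1, at 25.2 [4.33 to 1013], the neutrophil marker Il1r2 was at 2.13 and the monocyte marker Plac8 at 1.37. Under other settings the fatty acid uptake median ranged from -1.06 to 0.70, and within cluster 2 the medians were -0.78 for interferon, 0.37 for contractile and -0.38 for matricellular genes.

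Macrophage-monocyte-like cells of the library labelled Cre-positive held less transcript of inflammatory and more of alternative polarisation genes than those of Cre-negative bleomycin. All 9 inflammatory polarisation genes were lower, with a median of -0.61 [-1.02 to -0.47], among them Il1b at 316 CPM [257 to 385] against 824 CPM [754 to 897], a ratio of 0.384 [0.307 to 0.477], Nfkbia at 0.508 and Ccl4 at 0.654. Alternative polarisation genes had a median of 1.06 [0.76 to 1.48] with 9 of 10 higher, such as Mrc1 at 1.51, Folr2 at 1.58 and Clec10a at 2.00. Cluster 4, led by Ccl8, Folr2 and Clec10a among others, held 31.8% of the class in the library labelled Cre-positive and 11.7% in Cre-negative bleomycin. With each cluster given equal weight these medians were 0.48 for alternative and -0.31 for inflammatory polarisation, and they were 0.59 and -0.41 in thinned cells.

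Chemokines and cytokines had a median of -0.61 [-0.74 to -0.31], or -0.31 with equal cluster weights, with 10 of 13 members lower, including Cxcl1 at 0.0859 [0.0173 to 0.262] and Cxcl2 at 0.299 [0.246 to 0.361]. Ccl5, at 0.0205, had 74 of its 99 Cre-negative bleomycin UMIs in 1 cell. Spp1 (osteopontin) was at 0.229 [0.125 to 0.392], Ier3 at 0.392 and the lipase gene Lpl at 0.417. Higher were Ccl8 at 5.29 [4.07 to 6.93], Stard8 at 5.42, Fcgrt at 4.63, Apoe at 3.13 [2.84 to 3.45], Selenop at 2.69 [2.24 to 3.23], Fabp5 at 2.47 and Cd209f at 4.68, the Cre-negative bleomycin UMIs of Cd209f being in 1 cell. The p53 group had a median of 0.56 [0.19 to 0.80] with 14 of 15 members higher, although Cdkn1a was at 1.02 [0.893 to 1.16], and this median was 0.067 in thinned cells, with 9 and 44 cells left out. Of markers of other classes, the mast cell Cma1 had 0 UMIs against 61, at least 9.996-fold lower, the muscle gene Acta1 was at 2.43 [1.47 to 4.05] and Naaa at 1.53. Monocyte genes had a median of -0.07 [-0.22 to 0.07], with Ly6c2 at 0.847, and medians were small for interferon response (-0.18), antigen presentation (0.09), lipid-associated macrophage genes (-0.05), fatty acid uptake (0.31), fatty acid oxidation (-0.02), lipolysis (0.05), glycolysis (-0.11), dissociation stress (-0.18) and proliferation (-0.28).

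In endothelial-like cells (55 against 99), the fatty acid translocase gene Cd36 was higher in the library labelled Cre-positive, at 3604 CPM [3277 to 3956] against 1542 CPM [1354 to 1749], a ratio of 2.34 [1.99 to 2.75]. Depp1 was at 3.67, Galnt15 at 3.47, Rgcc at 3.23, Timp4 at 2.95 and Cst3 at 2.52. The venular adhesion genes Selp, at 0.157 [0.0691 to 0.315], and Sele, at 0.300 [0.146 to 0.570], were lower, and cluster 15, which they lead, held 4 of 55 cells against 51 of 99. Bst2 was at 0.431, Igfbp7 at 0.502, Atf3 at 0.342 and Fosb at 0.280, the last reversed under several settings. Medians were 0.51 [0.25 to 0.85] for p53, 0.44 for fatty acid uptake, -0.46 for dissociation stress, -0.63 for glycolysis and -0.69 for contractile genes, and over 4 members each -1.27 for complement and -1.34 for proteases. Fatty acid uptake was at -0.16 in thinned cells and dissociation stress at 0.17 with at most 5% mitochondrial UMIs, each of opposite sign, and p53 at 1.09 under that limit. The macrophage marker Lyz2 had 58 UMIs in endothelial-like cells of the library labelled Cre-positive against 3, a ratio of 24.6 [8.02 to 123].

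Keratinocyte-like cells (24 in each library) had all 15 dissociation stress members higher in the library labelled Cre-positive, with a median of 1.74 [1.47 to 2.25]. The Cre-negative bleomycin cells were at -2.35 against PBS, which by itself raises this median. Atf3 was at 11.5 [6.46 to 22.7], Egr1 at 7.62, Btg2 at 7.04, Zfp36 at 6.02, Jun at 4.64 and Fos at 3.34. Genes lower there included Krt10 at 0.228 [0.189 to 0.273], Krt77 at 0.137, Krtdap at 0.214, Sbsn at 0.253, Dmkn at 0.253 and the lipid elongase gene Elovl4 at 0.0752, and Krtdap and Sbsn reversed when each cell had equal weight. Krt77 UMIs came from 5 cells of each library, 238 of the 483 Krt10 UMIs of Cre-negative bleomycin came from 1 cell, and the fibroblast marker Gsn was at 0.584. Mural-like cells (22 against 21) had Sox5 at 3.72, Rsad2 at 3.07, Zeb2 at 2.95, Cacna1c at 2.93, Lpp at 2.84 and Jund at 2.49, and Ifi27l2a at 0.323, Fabp5 at 0.363, Bst2 at 0.405, Vim at 0.502, Igfbp7 at 0.550 and Ifitm3 at 0.596. The endothelial marker Egfl7 was also lower in mural-like cells, at 0.288 [0.146 to 0.532], and their cluster carried 7 of 14 endothelial markers. Skeletal muscle-like cells (67 against 26) came from different clusters, the Pax7-led cluster 9 with 17 of 26 cells and the Acta1-led cluster 10 with 57 of 67, and the fibre genes Lmod2 at 16.8, Sln at 10.8, Mb at 9.45, Vdac1 at 6.59, Tcap at 5.82 and Atp2a1 at 4.71 were higher. Crip1 at 0.0753, Zfp36 at 0.0957, Tmsb4x at 0.101, Nfkbia at 0.103, Rhoj at 0.107 and Fos at 0.118 were lower there, as were the fibroblast markers Col3a1 at 0.080 [0.0344 to 0.167] and Gsn at 0.487, and Mustn1 was at 2.44.

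Set directly against PBS, fibroblast-like cells of the library labelled Cre-positive had medians of 2.77 for p53 (2.71 with members at 0 placed at their bounds), 2.71 for interferon, 1.77 for antigen presentation, 1.21 for chemokines and 0.57 for complement. The collagen median was -0.77 [-1.02 to -0.65], with Col1a1 at 0.599 and Col3a1 at 0.485, so collagen was lower than in either Cre-negative library. The homeostatic matrix median was -0.12 [-0.34 to 0.24] and that of dissociation stress -0.90. Cdkn1a was at 53.8 [18.2 to 262] and Fn1 at 2.08. In macrophage-monocyte-like cells the medians against PBS were 3.74 for monocyte genes (2.30 at the bounds), -2.45 for alternative polarisation, 1.98 for inflammatory polarisation (1.90) and 2.31 for interferon response (1.90), and in endothelial-like cells 2.15 for p53 and 1.08 for interferon response. The fibroblast-like interferon and chemokine medians and the alternative polarisation median were the same at the bounds.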

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

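Tests without skeletal muscle-like cells and of neutrophil and macrophage markers over all deposited barcodes were chosen only after the results they measure were seen. So was the test with the same cluster weights in both libraries. Tests within fibroblast-like clusters 2 and 5 and without the 3 richest cells used settings added after the data were seen. All directions rest on the Cre label alone, and with 1 library per group no difference between classes or libraries was tested.

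The dissociation stress group, which holds immediate early genes such as Fos, Jun and Atf3, went in opposite directions in different classes. In the Cre comparison its median was -2.11 in fibroblast-like, -0.46 in endothelial-like and -2.955 in skeletal muscle-like cells, but 1.74 in keratinocyte-like and 1.04 in mural-like cells. The endothelial-like value had no stable sign, at 0.17 with at most 5% mitochondrial UMIs. In the bleomycin comparison it was 0.84 in fibroblast-like cells (2.03 without the 3 richest cells of each library), 0.845 in endothelial-like cells and -2.35 in keratinocyte-like cells. The opposite signs are the pattern itself, so they cannot test 1 dissociation effect shared by all cells of a library. Medians within fibroblast-like clusters 2 and 5 were -2.29 [-2.48 to -1.73] and -1.07 [-1.46 to -0.75]. They excluded a different mix of clusters as the whole cause in fibroblast-like cells. A dissociation effect that differs between cell types was not tested, and genotype cannot be told apart from the library, since libraries per group numbered 1.

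Collagen genes were lower in fibroblast-like cells of the library labelled Cre-positive, with a median of -0.76. The median was -1.48 [-1.72 to -1.23] within cluster 2 and 0.089 [-0.088 to 0.36] within cluster 5, where collagen was not lower, so those medians alone met neither outcome set for a different mix of clusters. The clusters differed in weight, cluster 5 holding 51.6% of the UMIs of the class in the library labelled Cre-positive and 35.8% in Cre-negative bleomycin, and cluster 6 1.31% and 16.9%. With the same weights in both libraries the median was -0.754 [-1.08 to -0.552], which argued against a different mix as the cause over the class. Depth per cell was argued against by a median of -1.32 in cells thinned to 1000 UMIs, and a few collagen-rich cells by a median of -0.67 without the 3 richest cells of each library. Genotype stays open because libraries per group numbered 1.

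Macrophage-monocyte-like and neutrophil-like shares of kept cells were lower in the library labelled Cre-positive than in Cre-negative bleomycin. All leukocyte classes together made up 30.6% [26.2 to 35.2] against 58.2% [54.4 to 61.9]. Among leukocytes alone, macrophage-monocyte-like cells were not lower, at 85.3% [78.0 to 90.9] against 80.3% [76.0 to 84.1]. Neutrophil-like cells were lower there too, at 0.775% [0.020 to 4.24] against 9.37% [6.68 to 12.7]. Without skeletal muscle-like cells the macrophage-monocyte-like shares were 31.0% [26.2 to 36.1] against 48.5% [44.6 to 52.5], so the larger number of muscle cells was not the whole cause. Removal by the gene and mitochondrial filters was argued against for neutrophils by a CPM ratio of 0.0470 [0.0383 to 0.0572] for S100a8 and S100a9 over all deposited barcodes, and for macrophages and monocytes by a ratio of 0.605 [0.587 to 0.623] for their markers. Neither a loss of cells to the filter behind the deposited barcodes, which held no fewer than 501 UMIs in either bleomycin library, nor a difference in dissociation yield was tested, and genotype stays open because libraries per group numbered 1.

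Complement and acute phase genes differed in direction between classes in the bleomycin comparison, with medians of 0.55 in fibroblast-like and -2.52 in macrophage-monocyte-like cells, a difference that was not tested. Adipogenic regulators had medians of 0.60 in mural-like and -2.34 in skeletal muscle-like cells in the Cre comparison, also untested, with Klf4 at 7.18 and 0.0613 in the same order. Among barcodes outside the comparisons, some held over 90% mitochondrial UMIs. They made up 14.9% [12.9 to 17.2] of Cre-negative bleomycin and 14.3% [11.9 to 17.1] of the library labelled Cre-positive. PBS held 0 of 401, or 0% [0 to 0.916].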

How the results depend on the processing

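Settings chosen after the data were seen were those without skeletal muscle-like cells, over all deposited barcodes, within fibroblast-like clusters 2 and 5 alone, with cluster 14 counted as fibroblast-like, with dendritic-like cells merged into the macrophage-monocyte-like class, with equal weights for its clusters, without the cell richest in a gene and without the 3 cells richest in a gene group. Alternatives were run, where at least 20 cells of each library remained (no minimum for thinned cells, 10 cells within single clusters), for fibroblast-like, macrophage-monocyte-like, endothelial-like and keratinocyte-like cells in the bleomycin and Cre comparisons, and not for mural-like or skeletal muscle-like cells or for the library labelled Cre-positive against PBS, whose values were not checked in this way. Over the settings run, 1559 of 1826 gene ratios stayed within their counting interval, 232 moved out of it and 35 reversed, where a reversal is a change of sign of a value whose interval as reported excluded equality. Of 1685 group medians, 1448 stayed within their interval, 209 moved and 28 reversed. Signs also changed in 7 of the gene ratios and 36 of the medians that moved, and in 11 and 137 of those that stayed. Of 180 shares, 136 stayed and 44 moved. No paired analysis was possible because each group held 1 library. Counting depth limited the macrophage-monocyte-like comparison with PBS, since that class held 21 PBS cells, and it held more wherever dendritic-like cells joined it. Thinning left out 8 of 51, 11 of 63 and 18 of 106 fibroblast-like cells in PBS, Cre-negative bleomycin and the library labelled Cre-positive, 2 of 21, 44 of 317 and 9 of 110 macrophage-monocyte-like cells, 13 of 59, 48 of 99 and 5 of 55 endothelial-like cells, and 16 of 56, 7 of 24 and 3 of 24 keratinocyte-like cells. Because a library held under 20 cells of the class, no ratio or median was obtained for keratinocyte-like cells in both comparisons with at least 500 genes, at most 5% mitochondrial UMIs or Leiden resolution 2.0, nor for macrophage-monocyte-like cells in the bleomycin comparison with at most 5% mitochondrial UMIs (8 PBS cells) or no doublet removal (18 PBS cells). Equal cluster weights gave no value for macrophage-monocyte-like cells in the bleomycin comparison, and some medians had under 3 members in smaller sets of cells or members. Moves under the settings with fewer cells or fewer members follow in part from that construction, and otherwise the cause was not tested. In the values that follow, shares are of kept cells unless stated, gene ratios and medians are on the log2 scale, and (bleomycin) and (Cre) name the comparison.

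With at least 500 genes per cell, the PBS library held 18.4% keratinocyte-like, 19.4% macrophage-monocyte-like and 0% neutrophil-like. With at least 500 genes per cell, the Cre-negative bleomycin library held 59.7% macrophage-monocyte-like and 0% neutrophil-like. With at least 500 genes per cell, the library labelled Cre-positive held 34.96% macrophage-monocyte-like, 0% neutrophil-like and 9.46% skeletal muscle-like. With at least 500 genes per cell, the fibroblast-like median (bleomycin) was -0.57 for adipogenic regulators. With at least 500 genes per cell, the fibroblast-like median (Cre) was 0.70 for fatty acid uptake. At the 500-gene minimum, the fibroblast-like gene ratio (Cre) was 0.54 for Apoe. At the 500-gene minimum, the macrophage-monocyte-like medians (bleomycin) were 1.11 for matricellular matrix, -0.27 for contractile genes, -0.0072 for TGF-beta response, 1.31 for chemokines, -1.22 for complement, 0.064 for adipogenic regulators, -2.25 for alternative polarisation, 0.94 for inflammatory polarisation, 1.88 for monocyte genes, -0.23 for antigen presentation, -0.054 for glycolysis and -1.86 for proliferation. At the 500-gene minimum, the macrophage-monocyte-like medians (Cre) were -0.15 for lipid-associated macrophage genes, -0.45 for inflammatory polarisation and 0.23 for antigen presentation. At the 500-gene minimum, the endothelial-like medians (bleomycin) were 2.14 for p53, 0.11 for adipogenic regulators and 0.43 for dissociation stress. At the 500-gene minimum, the endothelial-like median (Cre) was -0.096 for dissociation stress. With at most 5% mitochondrial UMIs, the PBS library held 4.62% macrophage-monocyte-like. With at most 5% mitochondrial UMIs, the Cre-negative bleomycin library held 11.4% endothelial-like, 1.87% keratinocyte-like, 7.68% neutrophil-like and 1.87% skeletal muscle-like. With at most 5% mitochondrial UMIs, the fibroblast-like medians (bleomycin) were 0.19 for collagens, 0.62 for proteases and -0.66 for adipogenic regulators. With at most 5% mitochondrial UMIs, the fibroblast-like gene ratio (bleomycin) was 4.05 for Fabp4. With at most 5% mitochondrial UMIs, the fibroblast-like medians (Cre) were -1.27 for collagens, -0.27 for basement membrane, -0.20 for matricellular matrix, -0.27 for complement, -1.06 for fatty acid uptake and -0.82 for lipid-associated macrophage genes. Under the 5% mitochondrial limit, the fibroblast-like gene ratio (Cre) was 1.47 for Dkk2. Under the 5% mitochondrial limit, the macrophage-monocyte-like medians (Cre) were -1.03 for inflammatory polarisation and -0.20 for antigen presentation. Under the 5% mitochondrial limit, the endothelial-like medians (bleomycin) were 2.57 for p53 and 0.46 for dissociation stress. Under the 5% mitochondrial limit, the endothelial-like medians (Cre) were 1.09 for p53 and 0.17 for dissociation stress. Under the 5% mitochondrial limit, the endothelial-like gene ratio (Cre) was 0.60 for Fosb. Without a mitochondrial limit, the PBS library held 15.1% fibroblast-like, 32.4% keratinocyte-like and 13.7% macrophage-monocyte-like. Without a mitochondrial limit, the Cre-negative bleomycin library held 5.73% fibroblast-like and 5.87% keratinocyte-like. Without a mitochondrial limit, the library labelled Cre-positive held 20.5% fibroblast-like. Without a mitochondrial limit, the fibroblast-like median (bleomycin) was -0.46 for adipogenic regulators. Without a mitochondrial limit, the fibroblast-like medians (Cre) were -1.11 for collagens and -0.75 for fatty acid uptake. With every mitochondrial share allowed, the macrophage-monocyte-like medians (bleomycin) were 1.08 for matricellular matrix, -0.18 for contractile genes, -0.045 for TGF-beta response, 1.29 for chemokines, -1.22 for complement, 0.039 for adipogenic regulators, -2.27 for alternative polarisation, 0.85 for inflammatory polarisation, 1.84 for monocyte genes, -0.33 for antigen presentation, -0.033 for glycolysis and -1.63 for proliferation. With every mitochondrial share allowed, the macrophage-monocyte-like medians (Cre) were -0.30 for chemokines, -0.29 for inflammatory polarisation and 0.27 for antigen presentation. With no doublets removed, the Cre-negative bleomycin library held 42.9% macrophage-monocyte-like. With no doublets removed, the fibroblast-like median (bleomycin) was 0.71 for dissociation stress. At Leiden resolution 0.5, the endothelial-like median (Cre) was -0.068 for dissociation stress. At Leiden resolution 0.5, the endothelial-like gene ratio (Cre) was 0.23 for Fosb. At Leiden resolution 2.0, the PBS library held 17.0% keratinocyte-like and 15.7% macrophage-monocyte-like. At Leiden resolution 2.0, the fibroblast-like gene ratio (bleomycin) was 1.53 for Fabp4. At Leiden resolution 2.0, the macrophage-monocyte-like medians (bleomycin) were 1.15 for matricellular matrix, -0.31 for contractile genes, -0.29 for TGF-beta response, 1.35 for chemokines, -1.26 for complement, 0.029 for adipogenic regulators, -2.24 for alternative polarisation, 0.87 for inflammatory polarisation, 1.88 for monocyte genes, -0.34 for antigen presentation, 0.0009 for glycolysis and 0.13 for dissociation stress. At Leiden resolution 2.0, the macrophage-monocyte-like median (Cre) was -0.35 for inflammatory polarisation. After clustering without listed genes, the PBS library held 16.2% macrophage-monocyte-like. After clustering without listed genes, the fibroblast-like medians (Cre) were 0.12 for complement, 0.64 for fatty acid uptake and -0.60 for antigen presentation. After clustering without listed genes, the fibroblast-like gene ratio (Cre) was 0.44 for Apoe. After clustering without listed genes, the macrophage-monocyte-like medians (bleomycin) were 1.12 for matricellular matrix, -0.13 for contractile genes, -0.29 for TGF-beta response, 0.37 for proteases, 1.33 for chemokines, -1.27 for complement, 0.043 for adipogenic regulators, -2.25 for alternative polarisation, 0.81 for inflammatory polarisation, 1.90 for monocyte genes, -0.46 for antigen presentation and 0.024 for glycolysis. After clustering without listed genes, the macrophage-monocyte-like medians (Cre) were -0.47 for inflammatory polarisation and 0.28 for antigen presentation. When listed genes were left out of clustering, the endothelial-like median (Cre) was -0.068 for dissociation stress. When listed genes were left out of clustering, the endothelial-like gene ratio (Cre) was 0.23 for Fosb. With classes set per cell, the PBS library held 16.2% macrophage-monocyte-like and the Cre-negative bleomycin library 15.6% fibroblast-like. With classes set per cell, the fibroblast-like medians (bleomycin) were -0.36 for collagens and -0.47 for TGF-beta response. With classes set per cell, the fibroblast-like gene ratios (bleomycin) were 7.22 for Fabp4 and -0.17 for Col1a1. With classes set per cell, the fibroblast-like medians (Cre) were -0.50 for collagens and -0.43 for antigen presentation. Under per-cell marker classes, the macrophage-monocyte-like medians (bleomycin) were 0.68 for matricellular matrix, -0.26 for contractile genes, -0.17 for TGF-beta response, 1.35 for chemokines, -1.19 for complement, -0.20 for lipolysis, -0.25 for adipogenic regulators, -2.23 for alternative polarisation, 0.80 for inflammatory polarisation, 1.90 for monocyte genes, -0.42 for antigen presentation, -0.020 for glycolysis and -1.61 for proliferation. Under per-cell marker classes, the macrophage-monocyte-like medians (Cre) were -0.15 for lipid-associated macrophage genes, -0.23 for inflammatory polarisation and 0.23 for antigen presentation. Under per-cell marker classes, the endothelial-like median (Cre) was 0 for dissociation stress. Under per-cell marker classes, the endothelial-like gene ratio (Cre) was 0.37 for Fosb. Under TMM factors, the macrophage-monocyte-like medians (bleomycin) were 4.94 for matricellular matrix, 3.36 for inflammatory polarisation, 4.39 for monocyte genes, 1.13 for antigen presentation and 0.16 for dissociation stress. Under TMM factors, the macrophage-monocyte-like medians (Cre) were -0.29 for interferon and -0.16 for lipid-associated macrophage genes. With the mean of per-cell CPM, the fibroblast-like medians (bleomycin) were 0.084 for collagens, 0.22 for basement membrane, 0.43 for matricellular matrix, 1.01 for complement and 3.57 for p53. With the mean of per-cell CPM, the fibroblast-like medians (Cre) were -0.98 for chemokines, -0.25 for p53, -0.53 for interferon, 0.61 for fatty acid uptake and -0.16 for adipogenic regulators. With the mean of per-cell CPM, the fibroblast-like gene ratios (Cre) were 0.42 for Enpp2 and -0.53 for Timp1. With the mean of per-cell CPM, the endothelial-like median (bleomycin) was 1.61 for dissociation stress. With the mean of per-cell CPM, the endothelial-like median (Cre) was -0.88 for dissociation stress. Under equal cell weights, the keratinocyte-like median (Cre) was 2.73 for dissociation stress. Under equal cell weights, the keratinocyte-like gene ratios (Cre) were 0.22 for Krtdap and 0.20 for Sbsn. At 1000 UMIs per cell, the fibroblast-like medians (bleomycin) were 0.13 for collagens, -0.013 for collagen processing, 0.35 for matricellular matrix, -0.23 for homeostatic matrix, 0.78 for TGF-beta response, 1.45 for complement, 1.93 for interferon, -0.93 for fatty acid uptake, -0.58 for adipogenic regulators, -0.67 for lipid-associated macrophage genes and 2.88 for antigen presentation. At 1000 UMIs per cell, the fibroblast-like medians (Cre) were -1.32 for collagens, -0.097 for homeostatic matrix, -0.41 for complement, -0.14 for p53 and -0.41 for interferon. At 1000 UMIs per cell, the fibroblast-like gene ratios (Cre) were 0.13 for Trps1, 0.037 for Dkk2 and -0.15 for Timp1. At 1000 UMIs per cell, the macrophage-monocyte-like medians (bleomycin) were 2.66 for matricellular matrix, 1.07 for contractile genes, -0.18 for TGF-beta response, 2.45 for chemokines, 2.69 for p53, -0.77 for fatty acid uptake, 1.07 for fatty acid oxidation and 3.25 for monocyte genes. At 1000 UMIs per cell, the macrophage-monocyte-like medians (Cre) were 0.067 for p53, -0.20 for lipid-associated macrophage genes, 0.59 for alternative polarisation and -0.41 for inflammatory polarisation. After thinning to 1000 UMIs, the endothelial-like medians (bleomycin) were 2.33 for p53, 2.13 for interferon, 1.05 for glycolysis and 0.51 for dissociation stress. After thinning to 1000 UMIs, the endothelial-like medians (Cre) were -0.16 for fatty acid uptake and -0.14 for dissociation stress. After thinning to 1000 UMIs, the keratinocyte-like median (Cre) was 2.59 for dissociation stress. With members of at least 5 UMIs, the fibroblast-like medians (bleomycin) were 0.34 for adipogenic regulators and 2.16 for antigen presentation. With members of at least 5 UMIs, the fibroblast-like median (Cre) was -0.38 for basement membrane. With members of at least 5 UMIs, the macrophage-monocyte-like medians (bleomycin) were 1.02 for matricellular matrix and -0.96 for complement. With members of at least 5 UMIs, the macrophage-monocyte-like median (Cre) was -0.65 for proliferation. Requiring 50 UMIs per member, the fibroblast-like medians (bleomycin) were 2.099 for interferon and -0.62 for adipogenic regulators. Requiring 50 UMIs per member, the fibroblast-like median (Cre) was -0.98 for collagens. Requiring 50 UMIs per member, the macrophage-monocyte-like medians (bleomycin) were 2.34 for p53, 0.93 for fatty acid oxidation and -3.04 for alternative polarisation. Requiring 50 UMIs per member, the macrophage-monocyte-like median (Cre) was 0.67 for alternative polarisation. Requiring 50 UMIs per member, the endothelial-like median (bleomycin) was 2.05 for p53.

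Without skeletal muscle-like cells, the library labelled Cre-positive held 29.9% fibroblast-like and 31.0% macrophage-monocyte-like. Of all deposited barcodes, the PBS library held 14.7% endothelial-like, 12.7% fibroblast-like, 14.0% keratinocyte-like and 5.24% macrophage-monocyte-like. Of all deposited barcodes, the Cre-negative bleomycin library held 9.24% endothelial-like, 5.88% fibroblast-like, 2.24% keratinocyte-like, 29.6% macrophage-monocyte-like, 3.45% neutrophil-like and 2.43% skeletal muscle-like. Of all deposited barcodes, the library labelled Cre-positive held 7.44% endothelial-like, 14.3% fibroblast-like, 3.25% keratinocyte-like, 14.9% macrophage-monocyte-like and 9.07% skeletal muscle-like. Within cluster 2 alone, the fibroblast-like medians (bleomycin) were 0.48 for collagens, 0.61 for proteases, 1.10 for complement, 3.67 for p53 and 0.35 for monocyte genes. Within cluster 2 alone, the fibroblast-like medians (Cre) were -1.48 for collagens, -0.38 for matricellular matrix, 0.15 for homeostatic matrix, 0.37 for contractile genes, -0.28 for complement, -0.78 for interferon and -1.62 for antigen presentation. Within cluster 2 alone, the fibroblast-like gene ratios (Cre) were 1.74 for Prlr, 1.43 for Dkk2, -0.41 for Fn1 and -2.35 for Timp1. Within cluster 5 alone, the fibroblast-like medians (bleomycin) were -0.79 for collagens, -0.022 for homeostatic matrix, 1.87 for chemokines, 1.18 for complement, 2.01 for interferon and 0.88 for lipid-associated macrophage genes. Within cluster 5 alone, the fibroblast-like gene ratios (bleomycin) were 2.41 for Hmcn2 and -0.63 for Col1a1. Within cluster 5 alone, the fibroblast-like medians (Cre) were 0.089 for collagens, 0.48 for matricellular matrix, 0.66 for TGF-beta response, -0.18 for p53, 0.67 for adipogenic regulators and -1.07 for dissociation stress. Within cluster 5 alone, the fibroblast-like gene ratios (Cre) were -0.38 for Inmt, -0.52 for Ccn5, 0.51 for Dkk2, 0.14 for Col3a1 and 0.038 for Col1a1. With cluster 14 counted as fibroblast-like, the fibroblast-like medians (bleomycin) were 1.58 for chemokines, 0.21 for complement and 2.07 for antigen presentation. With cluster 14 counted as fibroblast-like, the fibroblast-like gene ratio (bleomycin) was -0.027 for Col1a1. With cluster 14 counted as fibroblast-like, the fibroblast-like medians (Cre) were 0.21 for complement, 0.20 for interferon and -0.48 for antigen presentation. With cluster 14 counted as fibroblast-like, the fibroblast-like gene ratio (Cre) was 0.43 for Apoe. With dendritic-like cells merged in, the macrophage-monocyte-like medians (bleomycin) were 1.11 for matricellular matrix, -0.26 for contractile genes, -0.023 for TGF-beta response, 1.30 for chemokines, -1.25 for complement, 0.061 for adipogenic regulators, -2.29 for alternative polarisation, 0.87 for inflammatory polarisation, 1.86 for monocyte genes, -0.32 for antigen presentation, -0.01 for glycolysis and -1.61 for proliferation. With dendritic-like cells merged in, the macrophage-monocyte-like medians (Cre) were -0.31 for chemokines, -0.28 for inflammatory polarisation and 0.27 for antigen presentation. With dendritic-like cells merged in, the PBS library held 16.6% and the Cre-negative bleomycin library 50.8% macrophage-monocyte-like. With equal cluster weights, the macrophage-monocyte-like medians (Cre) were 0.0059 for matricellular matrix, -0.31 for chemokines, -0.17 for lipid-associated macrophage genes, 0.48 for alternative polarisation, -0.31 for inflammatory polarisation and 0.14 for monocyte genes. Without the top cell of the gene, the fibroblast-like gene ratio (bleomycin) was 0.017 for Fabp4. Without the top cell of the gene, the fibroblast-like gene ratio (Cre) was -0.38 for Timp1. Without the top cell of the gene, the keratinocyte-like gene ratios (bleomycin) were -1.99 for Mgll and 0.15 for Cst6. Without the 3 richest cells, the fibroblast-like medians (bleomycin) were 3.02 for chemokines and 2.03 for dissociation stress. Without the 3 richest cells, the macrophage-monocyte-like median (bleomycin) was 0.44 for dissociation stress. Without the 3 richest cells, the macrophage-monocyte-like medians (Cre) were -0.17 for lipid-associated macrophage genes, -0.29 for antigen presentation and -0.47 for dissociation stress. Without the 3 richest cells, the endothelial-like medians (bleomycin) were 2.49 for inflammatory polarisation and 1.12 for dissociation stress. Without the 3 richest cells, the endothelial-like median (Cre) was -0.75 for dissociation stress.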

Other observations

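Beyond the groups already described, keratinocyte-like cells of Cre-negative bleomycin had medians against PBS of 0.72 [0.17 to 0.98] for fatty acid uptake, 0.60 [-0.07 to 0.91] for fatty acid oxidation, -0.87 [-1.96 to -0.03] for TGF-beta response and -0.42 [-0.87 to -0.04] for glycolysis. Mural-like cells of the library labelled Cre-positive had a p53 median of 0.77 [0.02 to 1.12] and an antigen presentation median of -0.35 [-0.71 to -0.10] against Cre-negative bleomycin. Skeletal muscle-like cells, taken from different clusters in the 2 libraries, had medians of 1.22 for glycolysis, 1.06 for fatty acid oxidation and -1.81 for interferon response. Endothelial-like cells of the library labelled Cre-positive had medians against PBS of 0.51 [0.33 to 0.97] for adipogenic regulators, 0.52 [0.23 to 0.63] for fatty acid uptake and 0.86 [0.58 to 1.13] for antigen presentation.

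Over all kept cells, S100a8, an alarmin gene of neutrophils, stood at 12.04 CPM in PBS, 542 CPM in Cre-negative bleomycin and 43.5 CPM in the library labelled Cre-positive, and its partner S100a9 at 16.9, 1173 and 48.8 CPM. The skeletal actin gene Acta1 stood at 524, 929 and 6849 CPM and the smooth muscle actin gene Acta2 at 28.9, 67.4 and 42.6 CPM in the same order. Barcodes with over 50% of UMIs from haemoglobin genes, as in red blood cells, made up 24.7% [20.5 to 29.2], 11.5% [9.64 to 13.5] and 18.8% [16.1 to 21.8] of deposited barcodes. Barcodes with over 90% mitochondrial UMIs had a median of 21 detected genes in Cre-negative bleomycin and 20 in the library labelled Cre-positive.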
